A study of Homo sapiens with 6 samples.

How the data were processed

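Total RNA from 3 human glioma cell lines, U87, LN229 and U251, each transfected with miR-139-5p or with a negative control miRNA (miR-NC), was hybridised to 6 one-colour (Cy3) Agilent human gene expression arrays, 1 per line and transfection. The series is typed as sequencing and the sample descriptions speak of miRNA expression, but the deposited files are scanner output of mRNA arrays. The labels name no separate cultures, so p-values measure only the spread between these arrays, largely pooled over genes. That spread may be technical.

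The deposited scanner files hold spot intensity on a linear scale, and per the file headers the processed intensity was background-subtracted by Feature Extraction 10.5.1.1, whereas the submitters' processing notes name version 9.5.3. The authors' deposited table of normalized intensity equalled the processed signal of the scanner files in 45015 of 45015 rows on each array, so it holds no scaling between arrays. Each array carried 45015 spots, of which 1639 were controls. Between 73.9% and 79.6% of the other spots were well above background, none was saturated, and the median spot signal was 9.37 to 14.8 times its local background. The number of arrays limits the precision of every value.

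Values were log2 of the processed signal minus the 75th percentile of each array. Control spots and spots carrying an outlier flag (0.27% to 0.73% per array) were left out, spots of a probe were averaged, and probes well above background on at least 3 of the 6 arrays were kept (2 for the comparison of lines). A gene was represented by its passing probe with the highest mean signal. Of 40999 distinct probes, 26159 were given 1 gene symbol through the RefSeq accession of the probe or its Ensembl transcript, and 14840 stayed unnamed. Y-linked genes and X-inactivation RNAs (66 probes) were left out. This left 14510 genes. The genome build named in the headers contradicts itself, so no coordinates are given. Among 5193 genes with more than 1 passing probe, probes lay over 2-fold apart in 427 and moved over 2-fold in opposite directions in 6.

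The U87 and U251 arrays of the same transfection differed by less than the error that the scanner software gives for each spot. Over 29917 bright spots, the mean squared difference divided by that error was 0.59 for miR-NC and 0.65 for miR-139-5p, against 9.76 to 15.5 for the other 13 pairs of arrays. They were therefore averaged and counted as 1 sample, which leaves 2 samples per transfection: the averaged U87/U251 arrays, called the pair, and LN229. The averaging was decided after the arrays had been compared. The fit fixed before the data were examined took all 6 arrays as 3 replicates, and it is given as an alternative, with its count of changed genes beside the main one.

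Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, cell line as a block, Benjamini-Hochberg adjustment, threshold 0.05). The block was fixed beforehand because the arrays of each line share that line. The fit has 1 residual degree of freedom per gene, and its call count depends on a prior spread estimated over genes. That prior weighs as 4.53 degrees of freedom, so each SE and p comes mostly from it. Such a moderated SE is not the spread of 1 gene between 2 samples, and it was 0.291 for MMP3, SYNDIG1 and SCRG1 alike. In 30 simulated data sets with 14510 genes, of which 200 were changed, the same fit called 0.533%, 30.0%, 97.3% and 100% of genes changed by 1, 2, 4 and 8 on the log2 scale. On average 8.12% of its calls were false, and 16.8% in the worst data set, so the nominal 5% was exceeded. The prior degrees of freedom were estimated at 5.24 on average where 4.53 had been simulated, and 4 of 30 data sets with no change gave any call. Errors were drawn independently between genes, with spreads from the fit's own prior. Each change was equal in the pair and in LN229. The real data need not meet these conditions, so the simulated shares may be too favourable.

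Gene lists written from background knowledge before the data were examined were tested with camera (preset inter-gene correlation 0.01, two-sided, lists with at least 5 measured members), with camera using an estimated correlation, and with fry. With an estimated correlation camera takes its p from the residual degrees of freedom, 1 in the averaged fit and 2 on 6 arrays. So few let almost no list pass after adjustment. These p-values alone therefore do not decide whether inter-gene correlation accounts for a call. The correlation estimated on 6 arrays was 0.786 for interferon, 0.561 for mitotic and 0.509 for metallothionein genes, far above the preset 0.01. For the other called lists it lay between -0.0289 and 0.150. These estimates are themselves rough, but where they are that high the preset p is too small. A list's median in each line was also placed among 10000 random lists matched on mean expression. Seed sites of miR-139-5p (ACTGTAG, complementary to bases 2 to 8 of the miRNA, or CTGTAGA, which ends in an A) were searched in the longest 3' UTR of each gene in GENCODE 29, if at least 30 bases long. The median log2 fold change of genes with a site was compared with that of genes lacking the 6-base site, weighted over 25 bins of UTR length, with a bootstrap interval of 1000 draws over genes. Every 7-base word was ranked by its slope with UTR length and GC content as covariates. With site genes lowered by 0.3 in 10 simulated data sets of 13917 genes, a mean shift of -0.298 was recovered, and the seed word ranked no worse than 2 in the 3 data sets ranked.

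Where no array of a transfection had any probe of a gene well above background, the difference is given as "at least N-fold", the mean of the brighter transfection against, per array, the higher of the lowest signal well above background and the probe's own. Genes were named by a rule fixed before the data were examined: the 10 largest rises and falls past the threshold with 1 sign in all 3 lines, filled up by lowest p; all members of the reported miR-139-5p targets and the BCL2 family, and the host gene PDE2A; up to 4 members of every other list; the 5 largest rises and falls in each line; and the 5 genes per direction that set each line apart. The values of a few named genes and of 1 tested list are not printed. The alternatives tried were other background corrections, scalings, filters, probe summaries and priors, the fit without the cell line, and leaving out a line. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were also used.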

Results

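Gene expression was measured on 6 arrays from U87, LN229 and U251, established human glioblastoma lines, transfected with miR-139-5p or with the control miR-NC. The design asks which transcripts the miRNA alters in glioma cells. The 75th percentile of processed signal ran from 2510 to 4110 between arrays. Arrays labelled U87 and U251 were nearly identical within a transfection. The SD of their log2 difference was 0.169 for miR-NC and 0.177 for miR-139-5p, with 62 and 71 of 29917 spots over 2-fold apart. The other 13 pairs of arrays had SDs of 0.672 to 0.849 and 3018 to 5338 such spots. The U87 and U251 arrays differed by less than the scanner's spot error and were counted as 1 sample, so n = 2 per transfection in every test below unless 6 arrays are named.

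**Figure D1:**
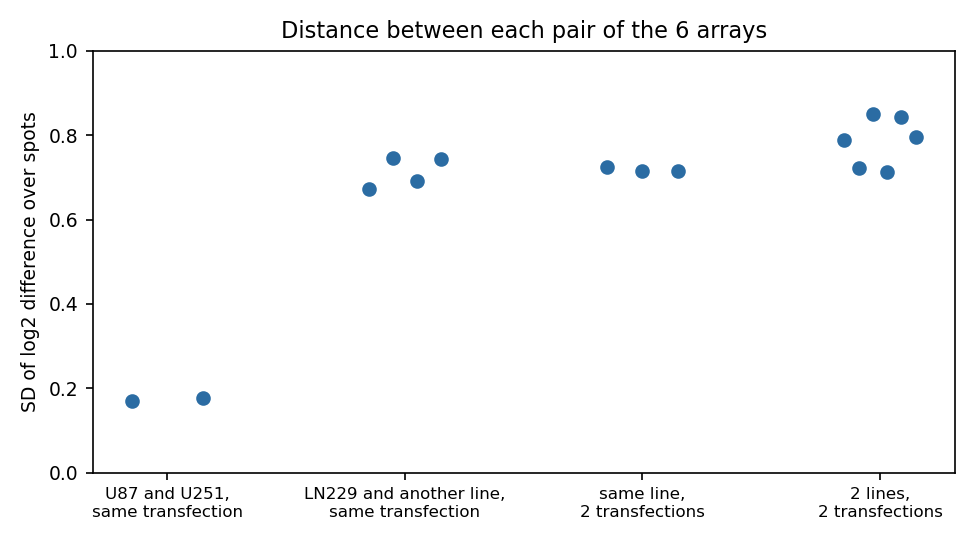
SD over 29917 spots of the log2 difference between 2 arrays (vertical axis, log2 units) for all 15 pairs of arrays, 1 point per pair, grouped by what the arrays share. The pairs of U87 with U251 arrays under the same transfection sit at 0.169 and 0.177, and all other pairs at 0.672 or above.

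Inflammatory mediators made up most of the named falls under miR-139-5p. CSF3, the granulocyte growth factor G-CSF, fell by 7.80 ± 0.62 on the log2 scale (moderated SE here and below, n = 2, limma adjusted p = 0.0286). The chemokine genes CCL20, CXCL11, CCL5 and CXCL8 also fell, with log2 fold changes of -7.30, -6.54, -4.79 and -4.49, and IL1B, which encodes the cytokine interleukin-1 beta, fell by 3.66. MMP3, a matrix metalloproteinase gene, fell by 5.74 ± 0.29 (adjusted p = 0.0173), and E2F3, a transcription factor gene of the cell cycle read by 1 probe here, fell by 6.90 ± 0.30 (adjusted p = 0.0147). SAA4 fell by 3.62. CCDC158 was not well above background on any miR-139-5p array and was at least 6.60-fold lower. The probes of CCL20, E2F3, CXCL11 and SAA4 were each dim on 1 of the 3 miR-139-5p arrays, so their folds rest partly on background. With dim signals raised to the lowest signal well above background E2F3 stood at -5.77, CCL20 at -6.22, CXCL11 at -5.42 and SAA4 at -2.49, and SAA4 no longer passed.

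Among the rises, SPARCL1, a matrix glycoprotein gene, went up in all 3 lines. It rose by 4.53 ± 0.30 (limma adjusted p = 0.0251) and SLC47A2, a transporter gene, by 4.72 ± 0.43 (adjusted p = 0.0421). The adhesion receptor gene ADGRL3 rose by 4.12, PPFIBP2 by 3.58 and the protocadherin gene PCDH19 by 3.09. On the miR-NC arrays SPARCL1, SLC47A2 and ADGRL3 were dim on 1 of 3 and PCDH19 on 2 of 3. With dim signals raised in the same way SPARCL1 stood at 3.39 and no longer passed, nor did RGMA and SCRG1. POSTN (periostin), SYNDIG1, RGMA and SCRG1 were not well above background on any miR-NC array and were at least 7.15-fold, 4.83-fold, 4.38-fold and 4.12-fold higher. SCRG1 stood at 5.08 in U87 but 2.71 in U251. Their average lay near the 3.88 of LN229, so its call rests on averaging 2 arrays that disagreed. Its SE was 0.291 in the averaged fit and 0.487 on 6 arrays. NELL2, named to fill the rule, was at least 3.07-fold higher and missed the threshold (adjusted p = 0.0532).

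In total 23 of 14510 genes passed limma's adjusted p of 0.05, 10 higher and 13 lower. This count was not stable: it was 561 with the 6 arrays taken as 3 replicates, 0 without the cell line in the model, 596 with normexp background correction, and 185 or 270 without the U87 or the U251 arrays. The control arrays also shared a spot spacing that no miR-139-5p array had, so scan and transfection cannot be told apart. The LN229 miR-139-5p array had a column spacing of its own, 23.11 pixels against 27.93 in U87 and 27.7 in U251. Differences in fold change between LN229 and the pair therefore cannot be told apart from the scan either.

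**Figure D2:**
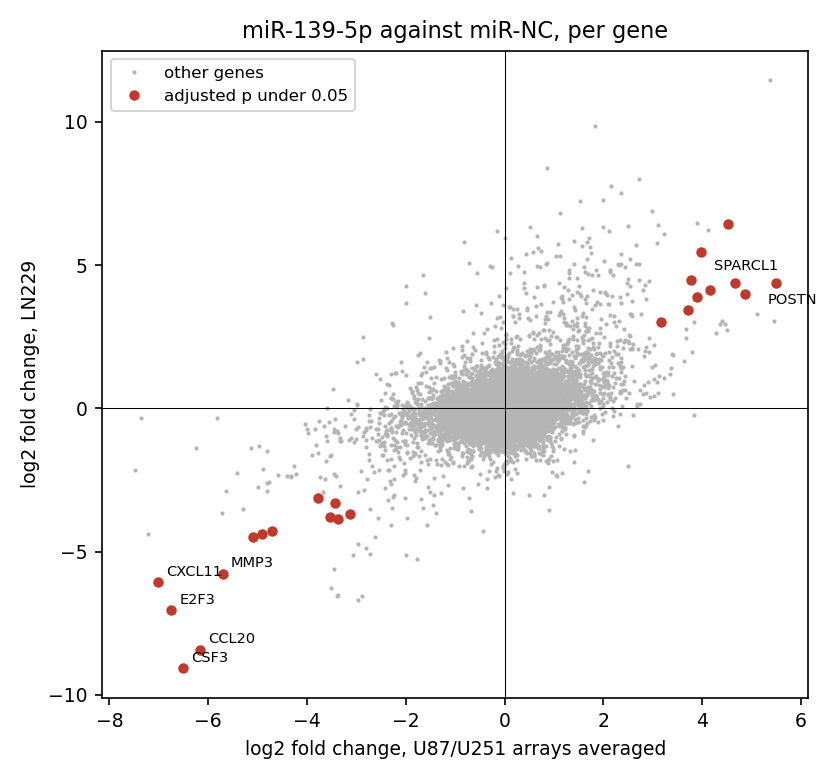
Log2 fold change of miR-139-5p against miR-NC for each of 14510 genes, in the averaged U87 and U251 arrays (horizontal) and in LN229 (vertical). Red points are the 23 genes past an adjusted p of 0.05, which lie near the diagonal. Pearson's r over all genes is 0.44.

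Among the lists, NF-kB and inflammatory genes were lower, with a median log2 fold change of -2.23. Of 27 measured members, 22 were lower in all 3 lines and 2 higher. Over all genes 51.6% shared a sign in all 3 lines, and here and below U87 and U251 count as 1 sample. In the pair and in LN229 the medians of the NF-kB list were -1.89 and -2.54. Of the list's genes 5 passed over all genes and 18 adjusted over the list alone (camera adjusted p = 2.4e-21, but adjusted p = 0.757 with an estimated correlation). Values with an estimated correlation, here and below, rest on 1 residual degree of freedom (2 on 6 arrays). They could hardly pass, and do not decide. Interferon response genes were lower too, with a median of -2.13 over 41 members, 39 of them lower in all 3 lines. The antiviral genes RSAD2, OASL and IFI44L had values of -5.81, -3.85 and -2.54 and did not pass over all genes. RSAD2 was dim on 1 miR-139-5p array. In this list 1 gene, CXCL11, passed over all genes and 35 adjusted over the list alone (camera adjusted p = 8.2e-31, but adjusted p = 0.757 with an estimated correlation). The median was -3.16 in the pair and -1.13 in LN229. Among 10000 random lists both medians lay at percentile 0.0 in each line, which was not so for every list that was called.

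Invasion proteases were lower (25 members, median -0.16, camera adjusted p = 0.0185, but adjusted p = 0.757 with an estimated correlation), with 1 passing over all genes and 4 adjusted over the list alone. MMP9 and MMP1 had values of -2.57 and -2.59, and MMP10, dim on all 3 miR-139-5p arrays, was at least 5.99-fold lower without passing. With the authors' unscaled table, where the median of all genes lies at 0.23, this list's median was 0.06, which is still below that of all genes. Metallothionein and oxidative stress genes were lower (23 members, median -0.23, adjusted p = 0.0337, but adjusted p = 0.810 with an estimated correlation and 0.116 with normexp). Their median was -0.34 in the pair and -0.04 in LN229 (percentile 12.0 of random lists), 0 passed on either adjustment, and MT1H stood at -1.01. Haematopoietic markers were lower (11 members, median -0.45, adjusted p = 0.0184, but adjusted p = 0.757 with an estimated correlation), with CD74, the invariant chain of MHC class II, at -2.35 and dim on 1 miR-139-5p array. Of these markers 0 passed over all genes and 1 adjusted over the list alone.

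Cholesterol biosynthesis genes were higher (23 members, median 0.72, camera adjusted p = 1.5e-07, but adjusted p = 0.757 with an estimated correlation), with 16 higher in all 3 lines and 0 lower. INSIG1 stood at 1.27, HMGCS1 at 1.35 and SQLE at 1.04. Markers of mesenchymal stromal cells (13 members, medians 0.92 in the pair and 0.70 in LN229, adjusted p = 4.1e-05) and of astrocytes (11 members, median 0.68, adjusted p = 9.4e-05) were higher, each with adjusted p = 0.757 with an estimated correlation. COL1A2 and PDGFRB stood at 2.08 and 1.77, FABP7, dim on 1 miR-NC array, at 4.93 and GFAP at 0.84. Mitotic genes were higher (36 members, median 0.40, adjusted p = 0.000233, but adjusted p = 0.757 with an estimated correlation), at 0.70 in the pair and 0.03 in LN229 (percentile 27.9 of random lists), with CDC25C at 1.43 and PRC1 at 0.89. Glioma tumour genes (19 members, median 0.33, adjusted p = 0.0084) and collagens and matrix genes (25 members, median 0.23, adjusted p = 0.0314) were higher, each with adjusted p = 0.757 with an estimated correlation, the latter at percentile 70.7 of random lists in LN229. SOX2 and PDGFRA stood at 2.71 and 1.73. Adjusted over the list alone, 1 cholesterol, 5 mesenchymal, 3 astrocyte, 0 mitotic, 2 glioma and 1 matrix gene passed. Over all genes only POSTN of these 6 lists did.

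**Figure D3:**
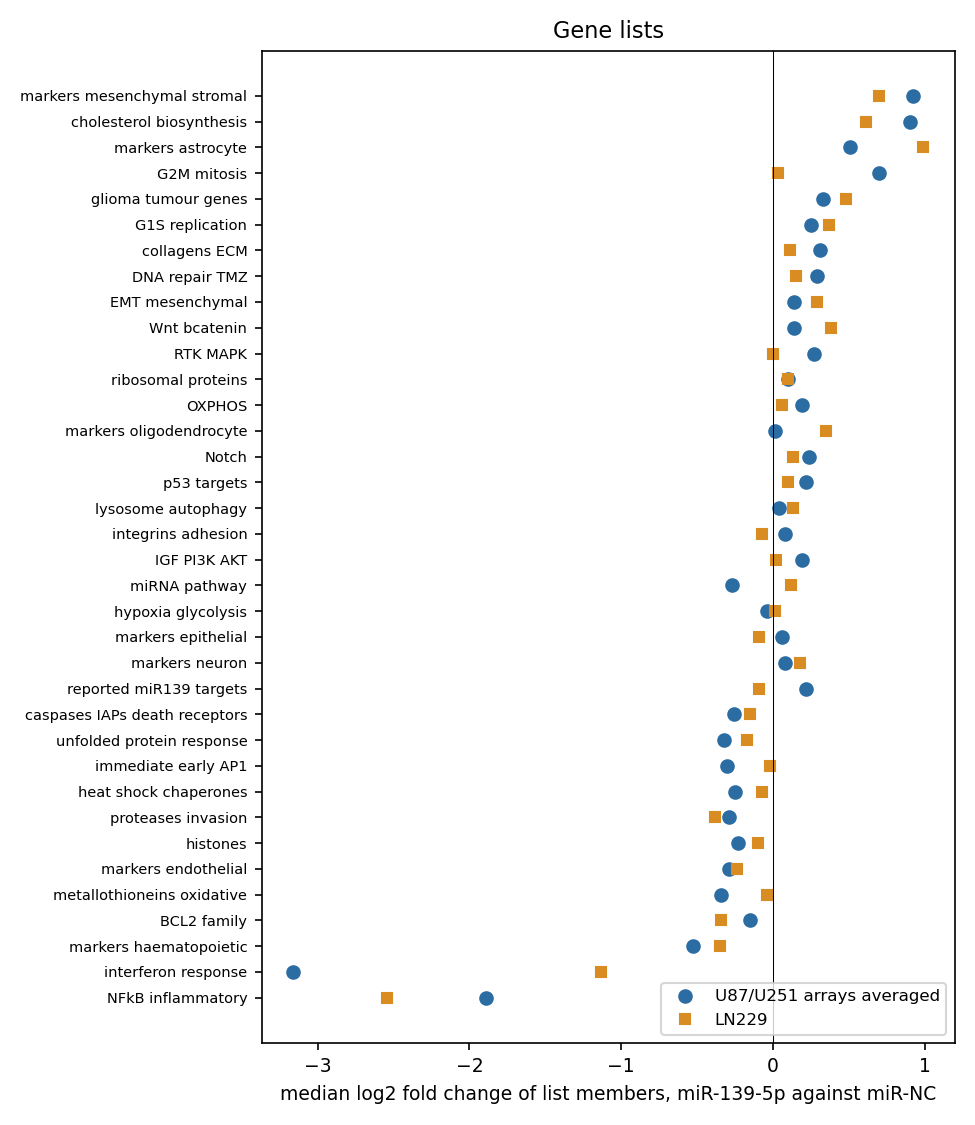
Median log2 fold change of the measured members of each gene list shown (horizontal axis), for the averaged U87 and U251 arrays (circles) and LN229 (squares), lists ordered by their overall median. NF-kB inflammatory genes lie at -1.89 and -2.54 and interferon genes at -3.16 and -1.13, below every other list.

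The other 26 lists did not pass camera, with adjusted p from 0.0907 to 0.833. Unfolded protein response genes passed with the mean of passing probes (0.0373), with trend and robust (0.0417) and on 6 arrays (0.0255), ribosomal proteins with trend and robust (0.0356) and histones on 6 arrays (0.0427). On 6 arrays both the unfolded protein response and the histone list had an adjusted p = 0.448 with an estimated correlation. Unfolded protein response genes had a median of -0.14 (adjusted p = 0.0907), histones -0.17, endothelial markers -0.23, heat shock chaperones -0.14, caspases, IAPs and death receptors -0.10 and immediate early genes -0.14. The miRNA pathway, p53 targets, IGF, PI3K and AKT genes, integrins, and lysosome and autophagy genes each lay at 0.03 or 0.04. Hypoxia and glycolysis genes stood at -0.01, Notch genes at 0.06, oligodendrocyte markers at 0.07, neuronal markers at -0.05 and epithelial markers at -0.03. DNA repair genes stood at 0.22, G1/S genes at 0.24, EMT genes at 0.21, Wnt genes at 0.18, RTK and MAPK genes at 0.13, and OXPHOS and ribosomal protein genes at 0.12. Over all genes 1 of these, POSTN in the EMT list, passed. Adjusted over the list alone 3 EMT, 2 RTK and MAPK, 2 integrin, 1 Notch, 1 Wnt and 1 oligodendrocyte gene passed. The mean and the median differed in sign for the miRNA pathway (mean -0.05), hypoxia genes (0.08), neuronal markers (0.19) and epithelial markers (0.02), and camera's direction was down for the miRNA pathway, hypoxia and epithelial lists and up for neurons. On the authors' unscaled scale the medians of the unfolded protein response, histone, chaperone, caspase, immediate early, hypoxia, neuronal and epithelial lists and of the reported targets lay above 0 and below the 0.23 of all genes. Medians near 0 also turned sign elsewhere. This held for hypoxia genes with normexp, median centring, outlier-flagged spots kept, without U87 and on 6 arrays, and for neuronal markers with no filter (0.27) and the floor (0.12). It also held for epithelial markers with no filter (0.16), the miRNA pathway on 6 arrays (-0.07) and with the mean of passing probes (-0.05), reported targets on 6 arrays (0.04), IGF, PI3K and AKT genes with the mean of passing probes (-0.09) and the filter on all 6 arrays (-0.04), and lysosome genes with the mean of passing probes (-0.07). On 6 arrays without LN229 the neuronal, epithelial, miRNA pathway and reported target medians turned sign. Setting dim genes to their bounds left every list's median as it was to 2 decimals.

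Genes reported elsewhere as miR-139-5p targets were not called as a group. The median over 25 was -0.06, while the mean (0.21) and camera's direction were above 0. Of the 25, 8 were lower and 10 higher in all 3 lines (camera adjusted p = 0.833), and 0 passed over all genes. Adjusted over the list alone CXCR4 and TPD52 passed. MCL1, an anti-apoptotic BCL2 family gene, had a value of -0.06 ± 0.31, at 0.14 in U87, -0.34 in LN229 and 0.30 in U251. Its other 2 probes gave -0.98 and -0.13, so the probes disagreed. The largest values were TPD52 at 3.59 and FOS at 1.41, and CXCR4 was at least 1.83-fold higher. The other probe of TPD52 gave 1.66. The lowest were RAB21 at -1.05, ETS1 at -0.94, JUN at -0.73, RUNX1 at -0.72, ADGRL4 at -0.54 and ROCK2 at -0.51. The 2 other probes of ETS1 gave -2.15 and -1.65, that of ROCK2 -0.82 and that of RUNX1 -0.08. The other probe of RAB21 had no value in U251 and gave -1.11 in U87 but -0.06 in LN229. With 6 arrays as 3 replicates RAB21 and ETS1 passed over all genes (limma adjusted p = 0.0407 and 0.0428). IGF1R stood at 0.85, where its other probe gave -0.12. MET stood at -0.36, where its other probes gave -1.15 and -1.09. MMP11, FOXO1, TCF4, LMO4 and TOP2A lay at 0.93, 0.54, 0.47, 0.42 and 0.62. ZEB1, EIF4G2, RAP1B, HNRNPF, HRAS, NR5A2 and NOTCH1 lay between -0.30 and 0.03. PDE2A, in which the miRNA is encoded, stood at 1.05 (adjusted p = 0.251, and 0.0441 with 6 arrays).

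The BCL2 family of apoptosis regulators had a median of -0.25 over 18 members (camera adjusted p = 0.107, and 0.0189 with the mean of passing probes), with 9 lower and 3 higher in all 3 lines. None passed limma's adjusted p over all genes or over the list alone. BIK and BMF, which promote apoptosis, had the lowest values at -1.35 and -1.03. BCL2A1 stood at -0.57, BBC3 at -0.40, BAK1 at -0.37, BCL2L1 at -0.35 and PMAIP1 at -0.33. BCL2L13, HRK, BOK, BCL2L2, BID and BNIP3 lay between -0.26 and -0.13. BNIP3L, BAX, BAD and BCL2L11 lay at 0.38, 0.30, 0.23 and 0.19.

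A miRNA lowers transcripts that pair with its seed, so genes with a seed site were set against matched genes. The 2529 genes with a 7-base site in the 3' UTR differed by -0.022 (95% bootstrap interval over genes -0.054 to 0.030) from genes without one. In the pair the shift was -0.009 and in LN229 -0.027. ACTGTAG ranked 10025 of 16384 words, where rank 1 is the strongest lowering. For sites in the coding sequence the shift was -0.028, with an interval of -0.066 to -0.003 that leaves out 0. For the 3' UTR an average lowering beyond 0.054 lies outside the interval. Genes are not independent, which this interval does not cover.

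**Figure D4:**
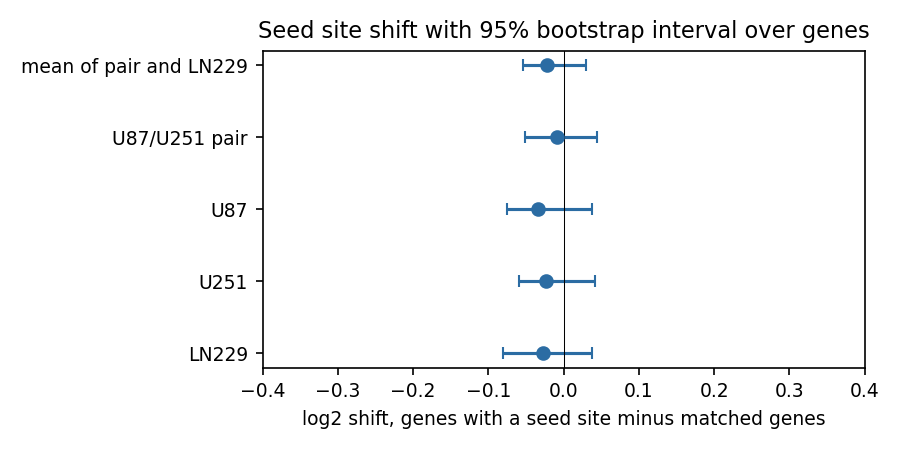
Median log2 fold change of genes with a seed site minus that of length-matched genes without one (horizontal axis, log2), for the mean of the pair and LN229, the pair, and each line. Bars are 95% bootstrap intervals over genes, and all 5 intervals include 0.

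Within single lines there was no replicate. The change exceeded 2-fold for 2060 genes in U87, 1780 in LN229 and 1962 in U251, and exceeded 5 on the log2 scale for 25, 69 and 22, or 13, 9 and 11 with normexp. The genes named here are the largest where the probe used was well above background on both arrays of the line. In U87 and U251 the largest falls were then in XAF1, RSAD2, CXCL11, E2F3 and CSF3, with XAF1 at -7.45 and -7.54. CXCL14, a chemokine gene, had the largest rise within this limit, 5.43 and 5.30. SPARCL1, RGS16 and STON1 were also among the 5 largest rises in both, with A2M in U87 (4.03) and HEYL in U251 (4.33). In LN229 the largest rises were PTN at 6.31, CCDC8 at 5.47, SULF2 at 5.43, HOXA5 at 5.33 and TPD52 at 5.15. The largest falls there, with the same limit, were CSF3 at -9.08, HOXA9 at -6.69, CXCL1 at -6.56, C3 at -6.55 and SAA1 at -6.26.

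Across genes, which are not independent replicates, the fold changes of U87 and U251 correlated with Pearson's r of 0.94 and Spearman's coefficient of 0.91. Those of LN229 correlated with r of 0.44 and a Spearman coefficient of 0.28 with each. The sign was shared by the pair and LN229 for 58.0% of genes, where chance gives 50%. All 3 lines shared it for 51.6%, which has no simple chance value since the U87 and U251 arrays are nearly identical.

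Between lines, 0 of 14817 genes passed limma's adjusted p for LN229 against the pair, with 1737 at an unadjusted p under 0.05. On 6 arrays 0 passed for U87 against U251, with 24 at an unadjusted p under 0.05. Also on 6 arrays, 0 passed for LN229 against U87 (3468) and against U251 (3581). The genes that set LN229 lowest apart were CCL5, SPARCL1, E2F3, ANGPTL1 and CA9, at -4.04, -3.68, -3.32, -3.09 and -2.75 against the pair. The ANGPTL1 probe was dim on 1 array of each transfection, that of E2F3 on 1 miR-139-5p array and that of SPARCL1 on 1 miR-NC array. These 3 differences therefore rest partly on background. The genes that set LN229 highest were TFCP2L1, MYLK2, HSD17B2, GINS4 and SIAE, at 2.22, 1.99, 1.93, 1.90 and 1.64. All 10 had an adjusted p of 0.193 or 0.194. For U87 against U251 every adjusted p was 1 among the genes the rule named, such as PPP1R1B at 0.44 and PTPN5 at -0.58.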

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

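The tests of the U87 and U251 arrays, of the scan batch and of the splits were chosen after the results were seen. The share of seed sites among inflammatory and interferon genes was predicted before it was computed.

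The U87 and U251 arrays of a transfection were nearly identical. Unscaled median spot signals already correlated at 0.9986 or more, so the likeness was present before scaling. The scaling used, 1 constant per array, cannot change a correlation, so this value was no test of it. The differences between U87 and U251 did not repeat over the transfections (r = -0.08 over spots, against 0.31 for LN229 with either line), which is consistent with the same RNA under both labels. Separate cultures of 1 line stay open, since the mean squared difference over the scanner error, at most 0.65, does not decide. The differences expected of 2 separate lines were not seen, and which label would be wrong was not tested.

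Inflammatory and interferon genes were lower on the miR-139-5p arrays. Direct pairing through the 3' UTR is argued against as the whole cause, since 7 of the 68 members (10.3%) held a seed site, against 18.2% of other genes (Fisher's exact test, two-sided, p = 0.113). That the control oligonucleotide raised these genes on the miR-NC arrays stays open, because 0 arrays were made without transfection. A difference between scan batches cannot be told apart from the transfection, because each batch held 1 transfection. With the batch as a random block and the cell line left out, 3 genes passed. An indirect effect of miR-139-5p remains possible and was not tested.

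For the 6 arrays taken as 3 replicates, the real split gave 561 genes and the highest of the other splits 0, with 1 of 10 splits reaching the real count. So few splits cannot give a share under 0.05. The other splits parted the arrays of only 1 line, or exchanged the transfections in 1 line. Each thus left the difference between transfections in the residual spread, which makes calls unlikely. The contrast of 561 with 0 therefore decides nothing.

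Some fold changes ran in opposite directions in LN229 and in the pair, and these differences were not tested. Over 2-fold in each, this held for 67 genes, against 639 that went the same way. The 67 became 11 with normexp, 38 with the filter on all 6 arrays and 101 with no filter. Scan and line cannot be told apart in these values, since the LN229 miR-139-5p array had a spot spacing of its own. Among the named genes with fold changes beyond 0.5 on the log2 scale in each, a limit chosen after the data were seen, the LN229 value minus that of the pair was 6.63 for NEFL, 2.96 for RBFOX3, 2.77 for NKX2-2, 1.83 for BCL2L11 and 1.48 for EIF4G2. It was -3.42 for CLDN5, -2.17 for ZEB1 and -1.19 for NOTCH1. A further 8 named genes had opposite signs with a value under 0.5 in at least 1 of LN229 and the pair. The NEFL probe was dim on 1 miR-NC array and that of CLDN5 on 1 miR-139-5p array.

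Outside the comparisons, probes with no gene name also differed from the control arrays. Of 9729 that passed the filter, 197 were over 2-fold higher and 95 over 2-fold lower in all 3 lines.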

How the results depend on the processing

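The fit on 6 arrays as 3 replicates had been fixed beforehand as the main one, and became an alternative when the averaging was chosen after seeing the data. Leaving out a line on 6 arrays and the scan batch as a block were added after seeing the data, and the other alternatives were fixed before. The count of changed genes, 23, depended on most choices: 596 with normexp (run on the median spot signal), 35 with quantile normalization, 231 with no filter, 101 with well above background on all 6 arrays, 126 with the floor, 9 with the authors' normalized table, 121 with trend and robust, 590 by 2-fold in all 3 lines with no test (274 with normexp, 347 with all 6 arrays), 561 with 6 arrays as 3 replicates, and 3 on 6 arrays with the scan batch as a random block and the cell line left out, which changes both at once. Without the cell line (no replicate block) it was 0, with 1056 at an unadjusted p under 0.05. Leaving out a line gave 185 to 270 genes in the averaged fit. On 6 arrays it gave 185 to 8994, the highest without LN229, where near-identical arrays stand as replicates. The averaged fit without LN229 has no residual degrees of freedom and gives no test. Median centring and outlier-flagged spots kept left 23. Of the 23 genes, 19 were also called with normexp, 8 with the filter on all 6 arrays, 9 with the authors' table and 23 on 6 arrays. The authors' table is unscaled, with a median over all genes of 0.23, and 3 of its 9 calls were higher. The cause of these shifts was not tested.

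Of 37 lists, 11 were called, against 0 with an estimated correlation, 0 by directional fry and 1 by mixed fry, the integrin list, which is not among the 11. On 6 arrays mixed fry called 31 and directional fry 0. The estimated correlation also gave 0 lists on 6 arrays, with a lowest adjusted p of 0.448. For the called lists, 183 values under alternatives kept the direction and call, 15 lost the call and 0 reversed by camera. Beside the estimated correlation, this was metallothionein genes with normexp, haematopoietic markers with no filter, and glioma genes with the mean of passing probes and on 6 arrays without LN229. The unfolded protein response, BCL2 family, ribosomal protein and histone lists gained a call in places, with adjusted p from 0.0189 to 0.0427. The seed shift stayed within its interval throughout. LN229 against the pair gave 370 genes with normexp, 3 with no filter and 3 with all 6 arrays, against 0. With the authors' unscaled table LN229 against U87 gave 601 and against U251 948, both on 6 arrays. With normexp 1335 genes in U87 and 907 in LN229 passed 2-fold. The LN229 count beyond 5 on the log2 scale, 69, was 9 with normexp (13 in U87 and 11 in U251), 16 with all 6 arrays and 32 with the floor. The r of the pair with LN229 was 0.39 with normexp, 0.38 with no filter and 0.38 with all 6 arrays, and that of U87 with U251 was 0.82 with no filter.

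Of 63 named genes, 796 values kept direction and call, 38 lost the call and 15 gained it. Another 18 reversed. With the authors' table these were MCL1 at 0.15, HRAS at 0.14, NR5A2 at 0.18, BCL2L2, BID and BNIP3 at 0.08, EIF4G2 and HNRNPF at 0.05 and RAP1B at 0.01. With 6 arrays they were MCL1 at 0.03, HRAS at 0.04, ZEB1 at 0.06 and BCL2L11 at -0.12. NOTCH1 was -0.12 with normexp and -0.08 with quantile normalization, BAX was -0.15 and NR5A2 0.26 with the mean of passing probes, and NR5A2 was 0.09 without replicate U251. Without replicate U87 NR5A2 kept its direction, at -0.16. Without LN229, which these counts leave out, the values of the pair had the other sign for ZEB1 (0.79), BCL2L11 (-0.72), HRK (0.41), BBC3 (0.30), HRAS (0.26), MCL1 (0.22), ADGRL4 (0.20) and PMAIP1 (0.02). The signal over background, 9.37 to 14.8, limits what dim probes can show.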

Other observations

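The tests on CDKN2A were chosen after its values were seen, and the gene lies outside the rule for named genes.

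CDKN2A, a tumour suppressor gene, was bright on every array. Its 2 probes were well above background on all 6 arrays, which argues against a signal from 1 cross-hybridising probe (2 of 2 probes). The lowest lay at percentile 97.1 of its array. U87, LN229 and U251 are widely described as lacking both copies of this gene, so a hypothesis is that the RNA may come from cells that keep it, which this level (97.1) is consistent with. Cross-hybridisation of both probes was not tested, and the files hold no genotype.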
